A study of Cannabis sativa with 12 samples.

How the data were processed

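Messenger RNA of leaves was sequenced in 12 samples of Cannabis sativa cultivar Pink Pepper. The groups and the replicate numbers 1 to 3 were taken from the sample titles. The labels do not say that the replicates were separate plants, so p-values measure the spread between these samples, which may be technical in part. Presence/absence genes (see Results) argue against repeats of the same plant within a group. Libraries of the same group differed in between 62 (control 1 and control 3) and 395 (putrescine 1 and putrescine 2) of these 738 genes. Of neighbouring genes in this set, 78.4% shared their pattern of libraries, against a shuffled mean of 9.24%. The spread within groups may thus also hold differences between plants or lines. Per the labels' protocols, RNA was extracted with a column kit and libraries were made with a poly(A)-based mRNA kit.

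Per the submitters' processing notes, the authors used fastp 0.24.0, STAR 2.7.11b, featureCounts 2.0.8 and DESeq2 1.44.0. Per the file headers, reads were counted per gene with featureCounts in paired mode without the option that counts read pairs, so both mates of a pair were counted. Between 63.9% and 68.8% of the counts above 10 in a sample were even. A count therefore stands for about 1 mate, not 1 fragment, and counting intervals are too narrow. The headers show no strand setting and no setting for reads mapped to several places; by default the first counts without strand and the second leaves such reads out. Reads of near-identical gene copies, of nuclear copies of mitochondrial genes and of overlapping or antisense genes are thus uncertain. The genome build is not given in the sources used here. Coordinates are those of the deposited files.

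The second deposited table per sample holds a normalized signal. For every gene it equals the deposited count divided by 1 size factor per sample (largest relative deviation 5e-15), and it lists the 21405 genes with more than 10 reads summed over the samples. It was used only for its size factors. The tests used the deposited counts.

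Gene identifiers were matched to the reference table of the Pink pepper assembly: 33721 by symbol, all with identical start and end, and 53 by locus tag, while 479 numbered tRNA genes were not matched. This table names 6 nuclear genes beyond their identifier and the mitochondrial genes, and it holds no product descriptions. The 30 gene lists set up before the data were examined relied on product descriptions, and 0 of them reached 3 members, so none was tested. In their place, lists were made from the names and classes in the table after the files had been seen: mitochondrial protein genes and their subgroups, mitochondrial rRNA and tRNA, named cannabinoid and terpene genes, long noncoding RNA, snoRNA, snRNA and each chromosome. No list for cell types other than the named trichome genes could be made. The rule for named genes had a fallback for missing product names, at most 2 identifiers per direction and comparison: those with the largest called change, a mean of at least 1 log2 CPM and, except for the interaction, no overlap between the groups. CHS, the cannabinoid genes and the mitochondrial examples were chosen after their values were seen.

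Counts were analysed with edgeR 4.0.16 in R 4.3.3: TMM normalization, low-count filtering by group (19328 of 34253 genes kept) and quasi-likelihood tests in 1 model of the 4 groups over all 12 samples, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every p-value called an adjusted p without another tool's name is from this edgeR fit or, for lists, from the tests named. The common biological coefficient of variation was 0.678. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM values (counts per library total, on the usual scale) use the TMM-scaled library sizes. Gene lists were tested on limma 3.58.1 voom values with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry, adjusted over 21 lists per comparison. Figures were drawn with matplotlib 3.10.9.

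The libraries held 36429915 to 49434127 counted reads, and 3 reads, the floor for a count of 0, correspond to at most 0.0823 CPM. Floors and counting intervals (95%, exact Clopper-Pearson) cover counting error only. No 2 libraries agreed within sampling noise: the closest pair, putrescine 2 and cold plus putrescine 2, had a Spearman correlation of 0.9786 and a median squared count difference 21.6 times the sampling value.

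The test was tested on simulated data with known answers. For cold against control it recovered 29% of genes changed 4-fold and 65% of genes changed 16-fold, with 1 false call among 19328 genes. For cold plus putrescine against putrescine it recovered 36% and 69%, with 3 false calls.

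Whether replicate numbers pair the samples was checked by correlating the deviations from group means of same-numbered libraries. For putrescine and cold plus putrescine the correlations were 0.38, 0.71 and 0.58 for numbers 1, 2 and 3. For cold and cold plus putrescine they were 0.17, 0.32 and 0.15. Both sets passed the rule that every pair exceeds 0.1. Control and cold plus putrescine passed it too (0.22, 0.31 and 0.16), and cold and putrescine did not (0.09, 0.32 and 0.14). The labels state no pairing, and the rule is weak: cold 3 correlated at 0.14 with a cold plus putrescine library of another number. Among the 738 presence/absence genes (see Results), putrescine and cold plus putrescine matched for numbers 2 and 3, with 0 differing. Their pair numbered 1 differed in 226 genes. Cold and cold plus putrescine pairs numbered 1, 2 and 3 differed in 187, 173 and 358. With the replicate number as a block, cold plus putrescine against cold gave 2143 genes, and cold plus putrescine against putrescine 0.

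Alternatives set up before the data were examined were other size factors (RLE, upper quartile and the authors'), 2 other low-count filters, DESeq2 1.42.0, limma-voom, the replicate block, fits of only the groups compared, 2 fold thresholds and leaving out each replicate. Added after seeing the data were counts halved to fragments, mitochondrial and rRNA genes left out, control 1 and cold plus putrescine 1 left out, cold plus putrescine 2 and 3 left out, and the replicate block in a fit of only the groups compared. Simulations of unchanged groups (20) gave the correlation and covariance that shared libraries alone produce. They cannot give an expected number of shared calls, since no gene differs in them.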

Results

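Leaf RNA of hemp (Cannabis sativa) cultivar Pink Pepper was sequenced in 12 samples, 4 groups of 3: control leaves at 23 °C, leaves held at 5 °C for 168 h (cold), leaves sprayed with 0.9 mM putrescine (putrescine), and leaves given both treatments (cold plus putrescine). Putrescine is a diamine that plants make themselves, and the series was set up to study how spraying it affects the response to cold. The labels state no temperature for the putrescine group, and the sprayed plants stood in a separate chamber, so spray and chamber cannot be told apart. The libraries held between 36429915 counted reads (cold plus putrescine 3) and 49434127 (cold plus putrescine 1). Of 34253 annotated genes, 19328 had enough reads to be tested. A floor of 3 reads in a library corresponds to at most 0.0823 CPM, the read count scaled to a common library size.

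The libraries also differed in which genes were at or near 0. In 738 genes every library lay either under 0.1 CPM or over 2 CPM, with both states present. The putrescine and cold plus putrescine libraries numbered 2 differed in 0 of these genes, and so did those numbered 3. The pair numbered 1 differed in 226 genes. Each of the other 64 library pairs, that one included, differed in at least 62 genes, with a median of 257.5. Of the 158 genes silent (under 0.1 CPM) in cold 3 alone, the largest set, 80 lay on chromosome X, between positions 2566544 and 83930785. The 92 genes silent in control 2 and putrescine 1 were all on chromosome 2, between 7892767 and 76323127, and 34 of 45 genes silent in putrescine 1 and cold plus putrescine 1 lay on chromosome 5 between positions 99411 and 1408330. Among neighbouring genes of this set, 78.4% shared their pattern of libraries, against a mean of 9.24% when patterns were shuffled over genes. A further 27 genes, all on chromosome 1, were silent in cold 1, 2 and 3, control 2, putrescine 1 and cold plus putrescine 1. Of the 1800 cold-responsive genes described next, 13 were presence/absence genes. Genes that switch within a group have a wide spread and are hard to call. The 13 therefore do not measure how far such library differences enter the calls.

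**Figure D1:**
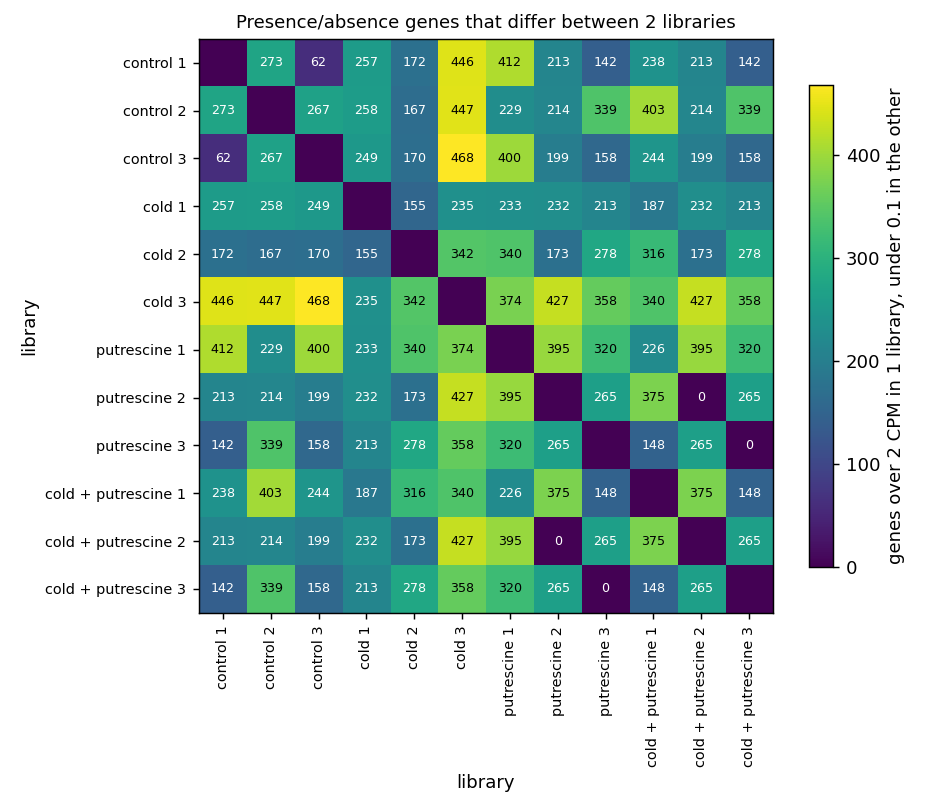
Number of presence/absence genes, out of 738, that were over 2 CPM in 1 library of each pair and under 0.1 CPM in the other; rows and columns are the 12 libraries, and colour and digits give the same count. The putrescine and cold plus putrescine libraries numbered 2, and those numbered 3, differ at 0 genes, while the next closest pair, control 1 and control 3, differs at 62.

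Cold against control asks how leaves changed over 168 h at 5 °C. Transcripts of the mitochondrial genome were more abundant in the cold leaves. Of 35 mitochondrial protein genes, 19 rose and 0 fell, with a median log2 fold change of 2.54 over all 35; adjusted over the list alone, 32 rose. The ATP synthase subunit gene atp9 rose from 5.2 ± 2.81 to 102 ± 68.8 CPM (log2 fold change 4.29, SE 0.7, edgeR adjusted p = 0.01). The complex I gene nad6 rose from 0.721 ± 0.453 to 17.8 ± 8.49 CPM and cox2, a subunit of cytochrome oxidase, from 8.97 ± 3.76 to 47.6 ± 25.2 CPM (SD, n = 3). By gene group, 5 of 8 nad genes, 4 of 4 cob and cox genes, 4 of 5 atp genes, 1 of 4 genes for cytochrome c maturation, 4 of 10 ribosomal protein genes and 1 of 2 sdh genes rose. Of 15 mitochondrial rRNA and tRNA genes, 1 was called and all 15 had positive log2 fold changes, with a median of 2.48 (camera adjusted p = 7.3e-06, adjusted p = 0.4 with an estimated correlation, and fry adjusted p = 0.013). The list of 35 stood above other genes in camera (adjusted p = 2.2e-14), a call lost with an estimated correlation (adjusted p = 0.4 with an estimated correlation). Its genes moved upward in fry (adjusted p = 0.013). The share of all reads from mitochondrial genes was 0.333% ± 0.213 in cold and 0.0614% ± 0.0398 in control. Most of this share was mitochondrial rRNA in every library, so it says little about the protein genes. Mitochondrial rRNA alone held 0.095%, 0.238% and 0.437% of reads in cold 1, 2 and 3. In control 1, 2 and 3 it held 0.082%, 0.0172% and 0.0466%. The rise of the whole mitochondrial share was uneven: cold 1, at 0.128%, lay near control 1 at 0.102% and level with putrescine 3. Control 2 was lowest at 0.0225%. The share from other rRNA genes was also higher in the mean, 1.15% ± 1.01 in cold against 0.388% ± 0.157 in control (SD, n = 3). Cold 3 carried that mean at 2.29%. Cold 1 was at 0.34% and cold 2 at 0.827%, against 0.288% to 0.569% in control. The count of 19 was 5 without control 2, 4 without control 3, 3 without cold 2 and 5 without cold 3; cox2 lost its call without control 2, control 3 or cold 2 (edgeR adjusted p = 0.05 to 0.058) and nad6 without cold 2 (adjusted p = 0.052).

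Chalcone synthase, the entry enzyme of flavonoid synthesis (gene CHS, LOC115724170, chromosome 9, 2012703 to 2014763), stood at 3100 ± 683 CPM in the cold leaves and 49.5 ± 41.9 CPM in control (SD, n = 3). The 3 cold libraries lay between 2380 and 3740 CPM, above the highest control library at 75.6 CPM. Its log2 fold change of 5.97 (SE 1.66) missed the threshold in edgeR, with an adjusted p of 0.051. It passed with DESeq2 (adjusted p = 1.6e-05) and limma-voom (adjusted p = 0.031), and adjusted p over all alternatives ranged from 1.6e-05 to 0.12. Genes of cannabinoid and terpene synthesis gave no call. Cannabidiolic acid synthase (CBDAS, LOC115697762) was at 6.04 ± 9.41 CPM in control and 6.89 ± 11.1 CPM in cold. Olivetolic acid cyclase (OAC, LOC115723438), which acts earlier in cannabinoid synthesis, was at 24.2 ± 33.4 and 10.5 ± 14.4 CPM. Most of their reads came from control 2 and cold 1: 862 and 912 of the CBDAS reads, and 3186 and 1256 of the OAC reads. Within the list of 4 genes that these make with the terpene synthase TPS1 (LOC115716064) and the polyketide synthase gene LOC115699293, 0 were called (camera adjusted p = 0.97).

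**Figure D2:**
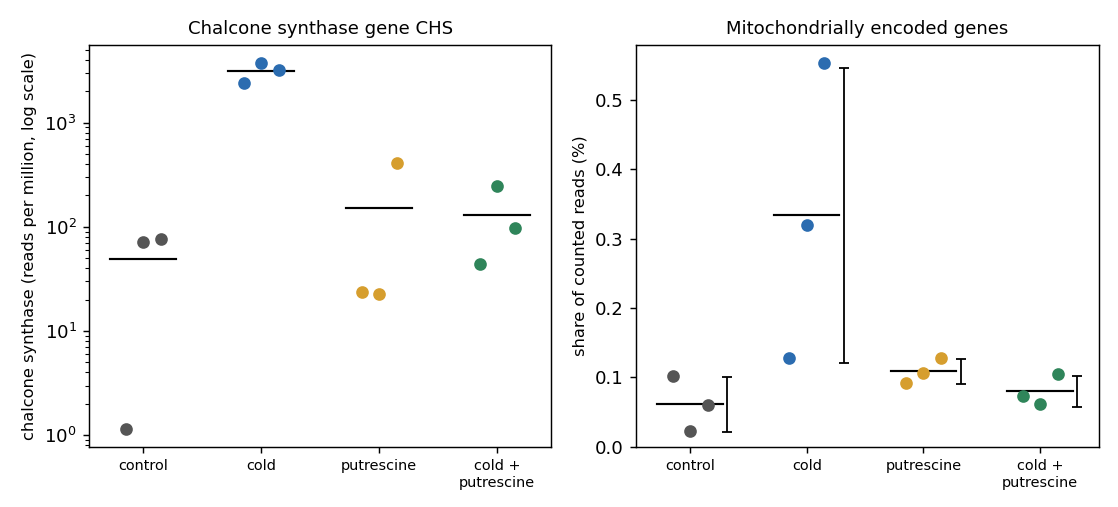
Chalcone synthase level in CPM (left, log axis) and share of counted reads from mitochondrially encoded genes in percent (right), by group; points are the 3 libraries, horizontal lines the mean, and bars on the right the SD. The cold libraries lie between 2380 and 3740 CPM for chalcone synthase, and the highest library of the other groups, putrescine 3, is at 413 CPM. Most of the share on the right is mitochondrial rRNA in every library.

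In all, edgeR called 1800 genes between cold and control, 1078 higher and 722 lower in cold, of which 852 and 463 changed at least 2-fold. In a check chosen after seeing the data the lower ones were longer: their median exonic length was 2562 bases over protein-coding genes, against 1578 for the higher ones and 1858 for genes not called. The change from the control mean fell with length in each cold library (Spearman rho = -0.201, -0.144 and -0.143), and in cold plus putrescine 1 (-0.115), with the other libraries between -0.0744 and 0.0715. The largest rises had no read in any control library. LOC115696962 (chromosome 7, 8242915 to 8247870) reached 1210 ± 618 CPM in cold, at least 16600-fold higher against a floor of 3 reads per control library (edgeR adjusted p = 0.017). LOC115723953 (chromosome 9, 57598279 to 57600911) reached 252 ± 227 CPM, at least 3460-fold higher in the mean (edgeR adjusted p = 0.012). Its cold libraries ranged from 15.5 to 467 CPM. The largest falls were LOC115720712 (chromosome 2, 54953924 to 54955357), from 8.19 ± 4.58 to 0.215 ± 0.241 CPM (log2 fold change -5.22, SE 1.24), and LOC115697652 (chromosome 7, 7022062 to 7024410), from 152 ± 63.3 to 4.86 ± 2.16 CPM (log2 fold change -4.96, SE 0.92). Among other RNA classes, 18 of 768 long noncoding RNA genes rose and 2 fell (camera adjusted p = 0.97). Of 122 snoRNA genes 1 fell, and their median log2 fold change was -0.428 (camera adjusted p = 0.047, and adjusted p = 0.56 with an estimated correlation; 0.05 to 0.36 without control 1, control 3 or cold 1). Of 14 snRNA genes 1 rose (camera adjusted p = 0.079). No chromosome as a whole, out of 10, stood apart in camera, where the lowest adjusted p was 0.19, for chromosome X. LOC115696962 lost its call without control 2 or cold 2 (edgeR adjusted p = 0.05 and 0.053), LOC115720712 without control 2, control 3 or cold 2 (0.05 to 0.11) and LOC115697652 without cold 2 (0.065). The count of 1800 was 595 without control 2, 967 without control 3, 943 without cold 1, 338 without cold 2 and 901 without cold 3. DESeq2 called 3984 genes, a fit of the control and cold groups alone 442, and the blocked fit 2577.

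Putrescine against control asks what the spray did without cold. No gene passed in edgeR (0 genes, with 806 at an unadjusted p under 0.05), DESeq2 called 95 and limma-voom 0. Chalcone synthase (CHS) was at 153 ± 225 CPM with putrescine and 49.5 ± 41.9 CPM in control, and 1 library, putrescine 3 at 413 CPM, carried that mean. The cannabinoid genes had lower mean levels in the sprayed leaves: OAC at 1.01 ± 0.898 CPM against 24.2 ± 33.4 CPM, and CBDAS at 0.054 ± 0.0935 against 6.04 ± 9.41 CPM (SD, n = 3). Control 2 carried both control means, with 3186 OAC and 862 CBDAS reads, while control 1 had 2 and 0, fewer OAC reads than any sprayed library (8 to 154). Neither difference passed (edgeR adjusted p = 1 for each). None of the 35 mitochondrial protein genes passed. Their median log2 fold change was 0.502, above other genes in camera (adjusted p = 6.3e-06) but not with an estimated correlation (adjusted p = 0.74 with an estimated correlation) or in fry (adjusted p = 0.76), and not without control 2 (camera adjusted p = 0.87). The share of mitochondrial reads, mostly mitochondrial rRNA, was 0.109% ± 0.0181 in the putrescine libraries, against 0.0614% ± 0.0398 in control. The share of nuclear rRNA reads was higher in the mean as well, 0.697% ± 0.62 against 0.388% ± 0.157. Putrescine 3 alone made that difference, at 1.41%, with putrescine 1 and 2 at 0.287% and 0.394%.

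Cold plus putrescine against cold asks what the spray changed in leaves kept at 5 °C. Mitochondrial transcripts were less abundant in the sprayed leaves. Of the 35 mitochondrial protein genes, 13 were lower with putrescine and 0 higher, with a median log2 fold change of -2.37; adjusted over the list alone, 33 were lower. The share of nuclear rRNA reads was lower in the mean too, at 0.56% ± 0.451 against 1.15% ± 1.01 in cold. Cold 3 carried the cold mean at 2.29%. Cold plus putrescine 1, at 1.06%, lay above cold 1 and cold 2 (0.34% and 0.827%). The gene atp9 stood at 7.25 ± 2.85 CPM, against 102 ± 68.8 CPM in cold (log2 fold change -3.81, SE 0.68, edgeR adjusted p = 0.013), and cox2 at 8.65 ± 1.01 against 47.6 ± 25.2 CPM (SD, n = 3). Camera placed the list below other genes (adjusted p = 1.8e-11, and adjusted p = 0.43 with an estimated correlation), and fry gave an adjusted p of 0.038. Both example genes lost their call without cold 2, cold plus putrescine 2 or cold plus putrescine 3 (edgeR adjusted p = 0.051 to 0.055). Chalcone synthase (CHS) was at 130 ± 106 CPM with putrescine and 3100 ± 683 CPM without, a log2 fold change of -4.57 (SE 1.55) that missed the threshold in edgeR (adjusted p = 0.095). Of the snoRNA genes, 2 of 122 rose, and the list stood above other genes (camera adjusted p = 0.0072, adjusted p = 0.43 with an estimated correlation, and 0.083 without cold 1). Of 14 snRNA genes 0 were called, with a list median of -2.19 (camera adjusted p = 0.025, and adjusted p = 0.43 with an estimated correlation). That call ended without cold 2, cold 3, cold plus putrescine 1 or cold plus putrescine 2 (adjusted p = 0.055 to 0.059).

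Between these groups edgeR called 1597 genes, 659 higher and 938 lower with putrescine, and 1231 of them changed at least 2-fold. The largest rises were LOC115697652, from 4.86 ± 2.16 to 248 ± 93.9 CPM (log2 fold change 5.67, SE 0.95), and LOC115698777 (chromosome 8, 24173025 to 24175364), from 1.06 ± 0.379 to 26.7 ± 7.05 CPM (log2 fold change 4.66, SE 0.89). LOC115708822 (chromosome 3, 4077602 to 4079989) fell from 70.6 ± 55.6 CPM to 0 reads, at least 933-fold lower against a floor of 3 reads per library. LOC115696962 fell from 1210 ± 618 to 0.065 ± 0.113 CPM, with 8 reads left in the 3 libraries (pooled ratio 17600, 95% exact counting interval 8940 to 40800). Without cold 2 none of these 4 genes passed (edgeR adjusted p = 0.053 to 0.083). LOC115698777 also lost its call without cold 3 (0.054), LOC115708822 without cold 1 (0.063), and LOC115708822 and LOC115696962 without any 1 of the cold plus putrescine libraries (0.057 to 0.075). The count of 1597 was 946 without cold 1, 283 without cold 2, 824 without cold 3, 1028 without putrescine 2, 835 without cold plus putrescine 1, 542 without cold plus putrescine 2 and 451 without cold plus putrescine 3. Leaving out cold plus putrescine 2 and 3 together, an alternative chosen after seeing the data, left 139 genes, and DESeq2 called 3740. With the replicate number as a block the count was 2143, and 1460 of the 1597 were among them. A blocked fit of only these 2 groups, also chosen after seeing the data, called 86, with 69 of the 1597 among them.

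Cold plus putrescine against putrescine asks how sprayed leaves changed in the cold. Genes moved by cold in unsprayed leaves had changes near 0 in sprayed ones. Over the 1078 genes higher in cold than in control, the median log2 fold change was 1.85 for cold against control and -0.0346 for cold plus putrescine against putrescine (quartiles -0.257 and 0.181). Over the 722 lower genes the medians were -1.2 and 0.0259. The 35 mitochondrial protein genes had a median of -0.223 (camera adjusted p = 0.55), and atp9 was at 7.25 ± 2.85 CPM with cold and 10.7 ± 5 CPM without. Chalcone synthase (CHS) was at 130 ± 106 and 153 ± 225 CPM (SD, n = 3). No gene passed in edgeR (0 genes, with 304 at an unadjusted p under 0.05), DESeq2 called 7 and limma-voom 0. On counts simulated for this comparison the same test recovered 36% of genes changed 4-fold and 69% of those changed 16-fold.

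**Figure D3:**
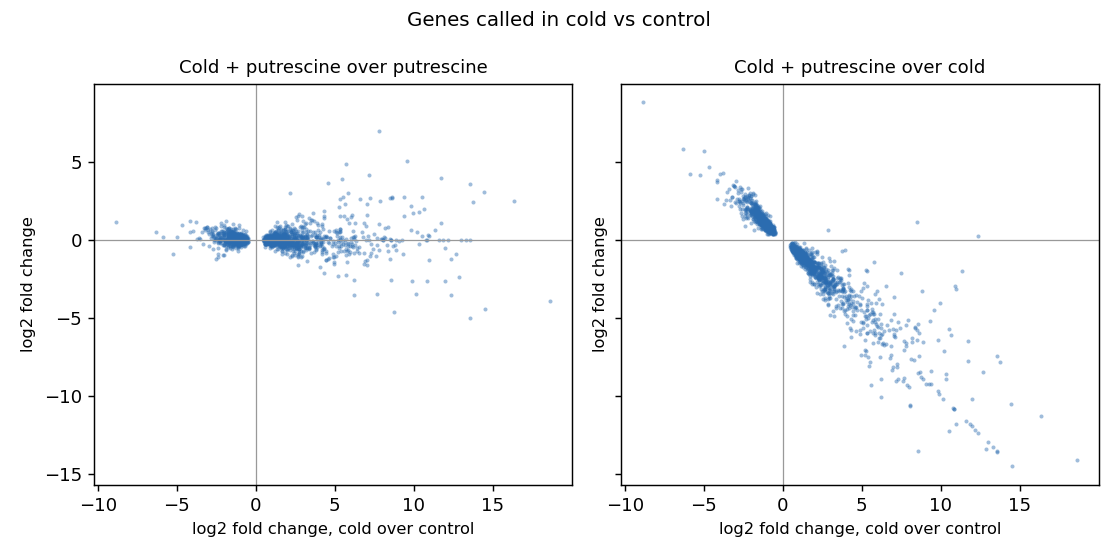
Log2 fold changes of the 1800 genes called between cold and control, on the horizontal axis, against their log2 fold changes for cold plus putrescine over putrescine (left) and over cold (right); each point is 1 gene, and values of genes with no reads in a group depend on the prior count of the fit. On the left the points spread around 0, with a median of -0.0346 for the genes higher in cold; on the right, which shares the cold libraries with the horizontal axis, the median of those genes is -1.68.

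The interaction asks whether the putrescine difference was another one in cold-treated leaves. It was called for 30 genes in edgeR, 6 positive and 24 negative, with 3482 at an unadjusted p under 0.05. LOC115708234 (chromosome 1, 20293426 to 20296184) stood at 189 ± 20.5 CPM in control, 32.8 ± 6.51 CPM in cold, 208 ± 27 CPM with putrescine and 229 ± 30 CPM with both (log2 interaction 2.66, SE 0.27, adjusted p = 0.015). LOC115707404 (chromosome 1, 44624553 to 44626139) was at 80.7 ± 3.53, 11.3 ± 2.97, 66.4 ± 9.79 and 90.3 ± 51.4 CPM in the same order (log2 interaction 3.28). LOC115698169 (chromosome 7, 51866847 to 51868790) was at 556 ± 369 CPM in cold and at 0.423 ± 0.102, 1.71 ± 1.62 and 1.41 ± 0.612 CPM in control, putrescine and both (log2 interaction -10.63). LOC115725692 (chromosome 6, 4288316 to 4289406) was at 93.9 ± 63.3 CPM in cold and under 0.5 CPM on average in each other group (log2 interaction -7.98, adjusted p = 0.05). None of the 35 mitochondrial protein genes was called; adjusted over the list alone, 23 were negative, with a median of -2.83 (camera adjusted p = 4.7e-14, adjusted p = 0.54 with an estimated correlation, and fry adjusted p = 0.092). Chalcone synthase (CHS) had an interaction of -6.2 (SE 2.05, edgeR adjusted p = 0.17). LOC115708234 lost its call without putrescine 2 or cold plus putrescine 3 (adjusted p = 0.071 and 0.085), LOC115698169 without any of 7 libraries (0.054 to 0.09), and LOC115707404 and LOC115725692 without any of 10 each (up to 0.13). The count of 30 was 204 without control 1, 5 without control 2, 13 without control 3, 15 without cold 1, 4 without cold 2, 12 without putrescine 1, 1 without putrescine 2 and 4 without putrescine 3. It was 5, 7 and 0 without cold plus putrescine 1, 2 and 3. It ranged from 1 with glmTreat and 4 with limma-voom to 417 in the blocked fit and 1704 with DESeq2.

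Whether cold acted alike with and without the spray was also read across all tested genes. Log2 fold changes of cold against control and of cold plus putrescine against putrescine, which share no library, had a Pearson r of -0.0482 and a Spearman rho of -0.0939 across 19328 genes, which are not independent replicates. Those of putrescine against control and of cold plus putrescine against cold had r = 0.0285 and rho = 0.0142. Of the 1800 genes called in cold, 1218 were also called between cold plus putrescine and cold, 1218 in the opposite and 0 in the same direction: 750 were higher in cold and lower with putrescine, and 468 the reverse. Independent lists of these sizes would share 52.3 and 24.6 genes. Both comparisons use the cold libraries, with opposite signs, which by itself favours opposite directions. Simulated unchanged groups shared 0 called genes, but no gene differs in them, so this 0 was near certain in advance and is no yardstick for 1218. The correlation was -0.504 simulated, against -0.747 observed. The covariance was -2.25 observed and -0.57 simulated. The difference was -1.68, where the simulated groups were independent and left out the likeness of same-numbered libraries. No split of the 3 cold libraries leaves 2 for each comparison, so part of the excess in the count and the correlation may come from the shared libraries. The count of 1218 fell to 479 without control 2, 710 without control 3, 666 without cold 1, 189 without cold 2, 608 without cold 3, 772 without putrescine 2, 736 without cold plus putrescine 1, 474 without cold plus putrescine 2 and 401 without cold plus putrescine 3.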

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

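All tests that weigh an explanation here were chosen after the results they bear on had been seen. The result singled out is the interaction, a test of whether the putrescine difference differs between cold-treated and other leaves, with 30 genes. It was called for LOC115707404 (3.28), LOC115708234 (2.66), LOC115698169 (-10.63) and LOC115725692 (-7.98), on the log2 scale. In 9 of 60 drawn splits that exchanged putrescine and unsprayed labels within each temperature, the real one included, at least as many genes were called. The highest of the other splits gave 605. Splits that keep the cold and the cold plus putrescine libraries apart retain the difference between those groups. The share of splits therefore does not measure chance, which is not excluded for this count. The 8 other splits that kept the cold and the cold plus putrescine libraries apart gave between 10 and 605 genes, and those that mixed them at most 30. The call of LOC115725692 was lost with limma-voom (adjusted p = 0.19), that of LOC115698169 likewise (adjusted p = 0.068), and that of LOC115707404 with RLE size factors (adjusted p = 0.052). Adjusted p for LOC115708234 rose to 0.071 without putrescine 2 and 0.085 without cold plus putrescine 3.

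The first pattern is that the cold plus putrescine libraries show no cold response. A score per library, the difference in mean log2 level between genes higher and lower in cold, was 1.47, 1.87 and 1.56 in the cold libraries. It was -2.32, -1.86 and -1.99 in cold plus putrescine, -2.18, -2.02 and -1.71 in putrescine and -2.47, -2.37 and -2.16 in control. Low power is argued against by the median of -0.0346 over the genes higher in cold, whose upper quartile lies below the lower quartile in cold against control (0.181 and 1.07). If sprayed leaves respond to cold, an exchange of labels would leave putrescine libraries with a cold score, and 0 of them reached the cold range. If putrescine held back the response, no sprayed library would have such a score under either labelling. The score therefore cannot exclude this exchange. The score does not test an exchange with control, since its genes were chosen between cold and control. Several explanations stay open and cannot be told apart. Putrescine, or the separate chamber of the sprayed plants, may have held back the response. These leaves may not have been cooled, or labels may have been exchanged. Of the cold plus putrescine libraries, 0 scored above every putrescine library. Of the genes higher in cold, 43.2% were also higher in cold plus putrescine than in putrescine. Each of these explanations allows these values.

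The second pattern is that same-numbered putrescine and cold plus putrescine libraries resemble each other. That 1 library stands under both labels is argued against for numbers 2 and 3, since their counts differ by at least 21.6 times the sampling value. A shared plant or line for numbers 2 and 3 may account for their likeness: 0 of the 738 presence/absence genes differed, where each other pair differed in at least 62. For number 1 a shared plant is argued against, with 226 genes differing. That pair still had 45 genes silent in both and in no other library, 34 of them on chromosome 5. The deviations from group means correlated at 0.38 within it, and at most at -0.2 between putrescine 1 and cold plus putrescine libraries of other numbers. A shared line that varies from plant to plant is thus not argued against for number 1. With other limits the pairs numbered 2 and 3 still differed least, in 4 and 2 of 1129 genes at limits of 0.2 and 1 CPM, against a median of 393 for the other pairs. A heritable line difference, a shared plant and a sample drawn from the other group were not separated by any test here.

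The third pattern is the higher level of mitochondrial transcripts in the cold libraries. Cold 3 alone is argued against, since the median log2 fold change of the 35 protein genes was 1.99 without it. More RNA lacking a poly(A) tail in the cold libraries could raise mitochondrial reads and nuclear rRNA reads together. The ratio used was that of all mitochondrial reads, protein genes included, to nuclear rRNA reads. In this ratio 4 libraries of the other groups reached the range of the cold libraries, which leaves this open. The ratio was 0.376, 0.386 and 0.241 in cold, 0.333, 0.0781 and 0.105 in control, 0.321, 0.269 and 0.0908 in putrescine, and 0.0684, 0.336 and 0.24 in cold plus putrescine. A response of mitochondria to cold stays open as well, and RNA integrity values per library were not used here.

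For cold against control, 1 of 10 splits of the 6 samples, the real one, gave as many genes (1800, highest other 11). For cold plus putrescine against cold it was 1 of 10 (1597, highest other 30). For putrescine against control all 10 splits gave at least the real 0 genes, highest other 2, and for cold plus putrescine against putrescine all 10 did, highest other 11. Every split reaches a real count of 0 by construction, so for these comparisons the splits decide nothing. In each comparison 10 splits are too few for a share under 0.05. For both comparisons of cold plus putrescine the numbers passed the rule for pairing, and 4 of the splits part every same-numbered pair. Apart from the real one those 4 gave 0 genes, and splits that part fewer pairs gave up to 30 and 11.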

How the results depend on the processing

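Tests marked as added were chosen after seeing the data: halved counts, mitochondrial and rRNA genes left out, the pairs of libraries left out, and the blocked fit of only the groups compared. The overlap held 0 genes in the same direction under each alternative run. Both comparisons use the cold libraries with opposite signs, which favours opposite directions in every fit. This 0 is therefore no measure of how robust the direction is. Where a value below changed, the cause was not tested, except that a fold threshold calls fewer genes by construction. For each comparison of 2 groups, the range with 1 replicate left out covers the replicates of those groups. Cold against control gave 3984 genes with DESeq2, 442 with only the groups compared, 55 with glmTreat, and 338 to 1338 with 1 replicate left out (1227 to 1895 without 1 of the sprayed libraries). Cold plus putrescine against cold gave 3740 with DESeq2, 73 with glmTreat, 139 without cold plus putrescine 2 and 3, 86 with only the groups compared and the replicate block, and 283 to 946 with 1 replicate left out (1028 to 2225 without 1 of the control or putrescine libraries). Putrescine against control gave 95 with DESeq2, 3 with the replicate block, 1 without control 1 and cold plus putrescine 1, and 0 to 2 with 1 replicate left out. Cold plus putrescine against putrescine gave 7 with DESeq2 and 0 under the others. The interaction gave 19 with RLE and 19 with the authors' size factors, 85 with upper quartile factors, 1704 with DESeq2, 4 with limma-voom, 417 with the replicate block, 1 with glmTreat, 124 with halved counts, 226 without control 1 and cold plus putrescine 1, 17 without cold plus putrescine 2 and 3, and 0 to 204 with 1 replicate left out. The overlap in opposite directions was 2791 with DESeq2, 38 with glmTreat, and 189 to 1154 with 1 replicate left out. The jackknife SE of the correlation was 0.13 for the cold effects and 0.17 for the putrescine effects. It is computed from the fits with 1 replicate left out, so those fits fall within it almost by construction. The other alternatives stayed within it too. With 1 replicate left out the correlations ran from -0.113 to 0.044 and from -0.0326 to 0.156. With the replicate block these were -0.16 and -0.0514, and control and cold gave 2577 genes; same-numbered control and cold libraries correlated at -0.087, 0.019 and -0.015, control and putrescine at -0.17, 0.0075 and 0.31, so those numbers do not pair the samples. Control and cold plus putrescine, which no comparison sets against each other directly, passed the rule for pairing (0.22, 0.31 and 0.16). Chalcone synthase turned sign, without a call, in cold plus putrescine against putrescine: 0.79 with limma-voom, 0.34 with the replicate block, 0.8 with only the groups compared and the block, 0.16 without control 1 and cold plus putrescine 1, and 2.5 and 0.16 without putrescine 3 and cold plus putrescine 1. In putrescine against control it ranged from -1.11, without putrescine 3, to 2.2 with 1 replicate left out. For the named genes, 404 of the alternative fits kept direction and side of the threshold, 110 lost the call, 7 gained it and 7 turned sign; for the list tests 106 kept both and 32 lost the call. Depth limits genes with few reads, since 3 reads correspond to up to 0.0823 CPM.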

Other observations

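The observations here, tests included, were made after seeing the data. Genes called between cold and control lay next to each other along the chromosomes more often than shuffled calls. There were 150 neighbouring pairs called in the same direction, against a mean of 86.9 and at most 117 in 10000 shuffles (p = 1e-04, the smallest these permutations can give). Without the mitochondrial genes there were 143, against a mean of 85.1 and at most 119 in 10000 shuffles (permutation p = 1e-04). On chromosome 6, 6 neighbouring genes between 66459146 and 66494746 rose in cold by log2 fold changes of 2.45 to 4.16, and 4 of them were called lower in cold plus putrescine than in cold. On chromosome 8, 4 genes between 41401866 and 41445727 rose by 5.36 to 12.7, and 4 were called lower with putrescine. On the mitochondrial genome 4 genes between 77529 and 88496 rose by 2.79 to 4.18. Reads shared between tandem copies were not examined. Whether chromosome blocks like those of the presence/absence genes add to these neighbouring calls was not tested.

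Genes of trichome chemistry varied between libraries of 1 group. OAC had 2, 3186 and 396 reads in the control libraries and 1256, 74 and 100 in the cold libraries, and the sprayed libraries held between 8 and 154. The gene LOC115696884, which the reference table also calls CBDAS2, had 0 reads in each of the 12 libraries, which allows up to 0.0823 CPM.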
